A study of Prunus avium with 27 samples.

How the data were processed

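Flower buds of sweet cherry were collected on 3 dates, and RNA and chromatin were prepared from frozen, ground buds of the same branches, per the labels' protocols. RNA came from 50 to 70 mg of tissue with an integrity number of at least 8.5 and was made into stranded libraries. Chromatin immunoprecipitation used 300 to 500 mg. All libraries were sequenced in paired reads of 75 bp, and per the labels all RNA libraries shared one lane and all H3K4me3 libraries another, so lane separates no dates. Groups were taken from the labels: 3 RNA libraries and 2 H3K4me3 libraries (replicates 2 and 3) per date. The 6 H3 and 6 input libraries have no values in the tables used here, so no background was subtracted and the subtraction planned as an alternative was not run.

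The RNA values are TPM as deposited by the authors, and each library summed to 1000000 over 29449 genes. The submitters' processing notes name TopHat and Picard for these libraries, without versions, and the program that computed the TPM and the genome build are not given in the sources used here. The H3K4me3 values are a normalised signal deposited by the authors, one per region and library, called TMM (trimmed mean of M values) per the file headers. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, Picard and DiffBind for them, without versions, roles or build. All values of each H3K4me3 library (100%, within 0.01 of a whole number) were whole multiples of one step, so each value was divided by that step. The numbers of steps, 14216613 to 28126160 per library, are treated as reads and called recovered reads. In each library 25.9% to 32.8% of regions stood at exactly 1 step, and 153 to 181 regions at 2 steps, so the lowest value is a minimum rather than a count of 1. Whether a control had been subtracted is not given in the sources used here, and if one had, the recovered reads are what was left and a region at the minimum can hold many reads. Depth behind the TPM is unknown, because TPM keeps none, and no counting intervals are given.

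Coordinates are as the tables give them. Because the build is not given, positions, gene order, gene starts and locus lengths need not be those of the sweet cherry genome. Of the 29449 identifiers, 28087 begin with PRUPE and 1362 with EPlPPEG, and 0 matched the RefSeq gene table of sweet cherry used for names (37283 genes), so identifiers stand without names. For that reason the 29 gene lists set up by name, their camera tests and the alternatives planned for them were not run. An identifier is given for 671 regions of H3K4me3, and all of them span 500 bp before the gene's start to 1500 bp into the gene (316 on the plus and 355 on the minus strand). Applying the same window to all regions assigned 23464 of 25635 (91.5%) to exactly 1 gene. The 2158 longer regions, 2144 of them holding windows of 2 genes, were tested as regions but not joined to RNA.

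RNA was tested with limma 3.58.1 (R 4.3.3) with an intensity trend on log2(TPM + 1), for 18384 genes with at least 1 TPM in at least 3 libraries, in one fit of all 9 libraries with date as the only factor. The contrasts were date 2 against date 1, date 3 against date 2, and date 3 against the mean of dates 1 and 2, with an F test over the 3 dates. Tests were two-sided, p-values were adjusted over the genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(value + pseudocount) scale. For H3K4me3 a count test had been planned, with limma as the choice if values were normalised. The deposited values being normalised, the same limma test was run on log2(signal + 1) for 15360 regions with a signal of at least 10 in at least 2 of the 6 libraries. The pseudocount and this filter for the signal were set after the values had been seen. With 2 libraries per date, the spread was shared over dates and moderated across regions. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives, and DESeq2 replaced its parametric dispersion trend by a local one. edgeR with the deposited scaling called 561, 171, 953 and 1440 regions for the contrasts in the order above and the F test.

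The tests, contrasts, thresholds, most alternatives and the rule for named items were chosen before the data were examined. The rule names, where identifiers have no names, the 2 largest rises and the 2 largest falls per contrast of adjacent dates, among called items with no overlap between the libraries of the dates and at least 5 TPM, or at least the median H3K4me3 level (a signal of 177.55), at the higher date. Items called in both assays were ranked by the product of their log2 fold changes, 2 per direction and contrast. H3K4me3 regions and jointly changed genes are given by position. The definition of gained and lost regions (signal of 20), the comparison with both scalings, the covariance with separate date 2 libraries, the counts in both assays without single H3K4me3 libraries, the regions with identifiers and the observations and tests under other observations were chosen after the data were seen, 2 of those tests before their own results, as said there.

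Joint analyses used 12773 genes tested in both assays, with Spearman correlations across genes, the overlap of calls against the product of the margins, and Fisher's exact test. For changes over both intervals, which share the date 2 libraries, 20 simulations without any change gave the value due to sharing. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

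The fits were tested on simulated data with 200 changed items of known size. For RNA, date 2 against date 1 over 18384 genes, limma recovered 35.8%, 83.6% and 97.0% of changes of 0.5, 1 and 2 log2 units, and 2.70% of its calls were false. For H3K4me3, date 2 against date 1 over 15360 regions, limma recovered 37.3%, 79.1% and 87.9% with 11.7% false calls, above the nominal 5%, and edgeR recovered 20.9%, 79.1% and 84.8% with 9.56% false. Alternatives were other pseudocounts, filters, scalings and tests, a replicate block, fits of the compared dates alone, a 2-fold threshold and leaving out each library. The planned count tests on RNA were not run, because the RNA values are TPM.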

Results

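Sweet cherry flower buds of the cultivar Burlat were sampled on 21 October 2014 (date 1), 5 December 2014 (date 2) and 27 January 2015 (date 3), 45 and 53 days apart. The labels call the buds of dates 1 and 2 dormant and those of date 3 non-dormant, and the series asks how chromatin and gene expression change together over dormancy. Date 3 is the only date labelled non-dormant, so dormancy label and date cannot be told apart. The 27 samples comprise 9 RNA libraries (3 per date) and 18 libraries from chromatin immunoprecipitation, with 2 per date for each of 3 kinds. These are 6 libraries of H3K4me3, histone H3 trimethylated at lysine 4, a mark found at the starts of transcribed genes, and 6 of H3 and 6 of input chromatin, which are not analysed here. The RNA tables list 29449 genes in TPM (transcripts per 1000000), a unit that keeps no depth, and 17105 to 18097 genes per library reached 1 TPM. The H3K4me3 tables give a normalised signal for 25635 regions, most of them at gene starts, all of them whole multiples of 1 step per library. The steps, 14216613 to 28126160 per library, are treated as reads here, although whether a control had been subtracted is not given in the sources used here. Gene identifiers are given without names or functions, because the tables pair them with none. The genome build is not given, so positions, gene starts and gene order need not be those of sweet cherry. The labels do not say whether replicates came from separate trees, so p-values measure the spread between these samples.

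RNA libraries grouped by date. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.972 to 0.984 between libraries of one date. They averaged 0.890 between dates 1 and 2, 0.950 between dates 2 and 3, and 0.871 between dates 1 and 3. The first principal component held 61.1% of the variance and set date 1 apart from the later dates. For H3K4me3 the correlations across regions were 0.945 to 0.959 within a date. Between dates they averaged 0.913 for dates 1 and 2, 0.937 for dates 2 and 3, and 0.873 for dates 1 and 3. The H3K4me3 libraries of one date stood apart on the first components. On the first, with 49.6% of the variance, those of date 2 lay at 17.9 and -18.5. On the second, with 25.3%, date 1 replicates 2 and 3 lay at 55.6 and -16.4. Date 1 replicate 2 and date 3 replicate 3, with the fewest recovered reads, lay highest there (55.6 and 24.3). Date 2 replicate 3, with the most, lay lowest (-44.7), and the part of depth in this spread was not tested.

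Between October and December, within the period labelled dormant, RNA levels changed for 11117 of 18384 tested genes (60.5%), with 5311 higher and 5806 lower at date 2. Changes of at least 2-fold were mostly falls, 2355 genes against 1055 that rose. Among genes at 5 TPM or more, the largest rise was that of PRUPE_ppa011907mg (scaffold 1, 1500014 to 1500980), which had 0, 0 and 0.326 TPM in the date 1 libraries and 237, 168 and 115 TPM at date 2. The level of EPlPPEG00000013796 (scaffold 4, 26995657 to 26995771) was listed at 0 in all 3 date 1 libraries, was 82.6, 66.0 and 53.6 TPM at date 2, and was 0, 169 and 143 TPM at date 3. PRUPE_ppa000511mg (scaffold 2, 18869663 to 18873987) fell from 137.8 ± 10.2 to 0.734 ± 0.193 TPM (mean ± SD, n = 3), and PRUPE_ppa012360mg (scaffold 7, 20209026 to 20209773) fell from 145 ± 20.1 to 1.00 ± 0.609 TPM. On the log2(TPM + 1) scale, which understates the change of low genes, PRUPE_ppa011907mg changed by 7.25 (SE 0.23). EPlPPEG00000013796 changed by 6.07 (SE 1.53), PRUPE_ppa000511mg by -6.33 (SE 0.16) and PRUPE_ppa012360mg by -6.23 (SE 0.31). Tested EPlPPEG identifiers varied more between libraries of a date, with a median SD of 1.27 log2 units against 0.16 for PRUPE identifiers. In limma with Benjamini-Hochberg adjustment, the adjusted p was 8.84e-09 for PRUPE_ppa011907mg, 0.00585 for EPlPPEG00000013796, 3.11e-09 for PRUPE_ppa000511mg and 1.35e-07 for PRUPE_ppa012360mg. The excess of falls over all called genes depended on the scaling: quantile normalization gave 6257 rises and 5148 falls. With library medians aligned there were 5596 rises and 5791 falls, and 2297 falls against 1083 rises of at least 2-fold.

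**Figure D1:**
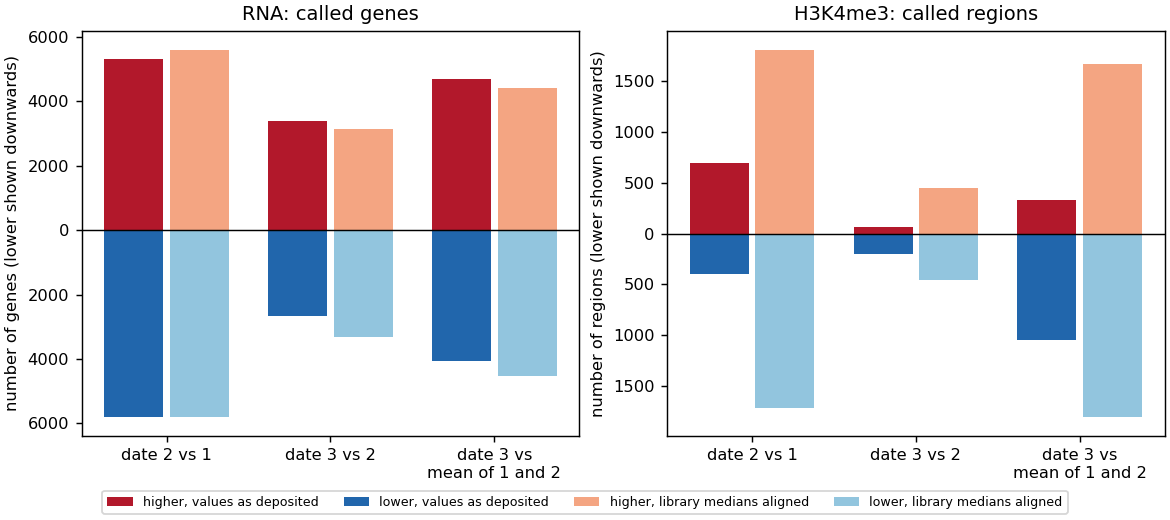
Numbers of RNA genes (left) and H3K4me3 regions (right) past an adjusted p of 0.05 in limma, higher above and lower below the 0 line, for each comparison of dates; dark bars use the deposited values and light bars the values with library medians aligned. RNA changes number 11117 between dates 1 and 2 and 6056 between dates 2 and 3 as deposited, while H3K4me3 counts rise from 1083 to 3523 and from 266 to 901 with medians aligned.

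Between December and January, when the labels turn from dormant to non-dormant, 6056 genes changed (32.9%), 3397 of them higher and 2659 lower at date 3. At 2-fold or more, 480 rose and 541 fell. EPlPPEG00000013528 (scaffold 2, 13219444 to 13219553) had 32.4, 0 and 0 TPM at date 2 and 60.7, 79.6 and 85.0 TPM at date 3. PRUPE_ppa013980mg (scaffold 3, 17445858 to 17446271) rose from 2.43 ± 1.22 to 65.7 ± 47.0 TPM (mean ± SD, n = 3), after 125 ± 12.7 TPM in October. The neighbouring genes PRUPE_ppa021384mg (scaffold 5, 10107138 to 10107696) and PRUPE_ppa022712mg (scaffold 5, 10104606 to 10105143) peaked in December. PRUPE_ppa021384mg stood at 2.24 ± 0.718, 112.8 ± 6.51 and 1.19 ± 2.06 TPM over the 3 dates, and PRUPE_ppa022712mg at 25.6 ± 3.69, 184 ± 30.2 and 3.88 ± 4.06 TPM. From date 2 to date 3 their log2(TPM + 1) changed by -6.10 (SE 0.49) and -5.54 (SE 0.42), with an adjusted p of 1.25e-05 for PRUPE_ppa021384mg and 9.96e-06 for PRUPE_ppa022712mg (limma, Benjamini-Hochberg). The changes of EPlPPEG00000013528 and PRUPE_ppa013980mg were 4.55 (SE 1.08) and 4.12 (SE 0.42), with an adjusted p of 0.00891 and 6.15e-05 (limma, Benjamini-Hochberg). The call of EPlPPEG00000013528 was lost without the filter on low values, where its limma p after Benjamini-Hochberg adjustment was 0.0652 (5.47e-06 to 0.0652 over its alternatives). With library medians aligned, 3137 genes rose and 3306 fell, so the excess of rises among all called genes turned.

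**Figure D2:**
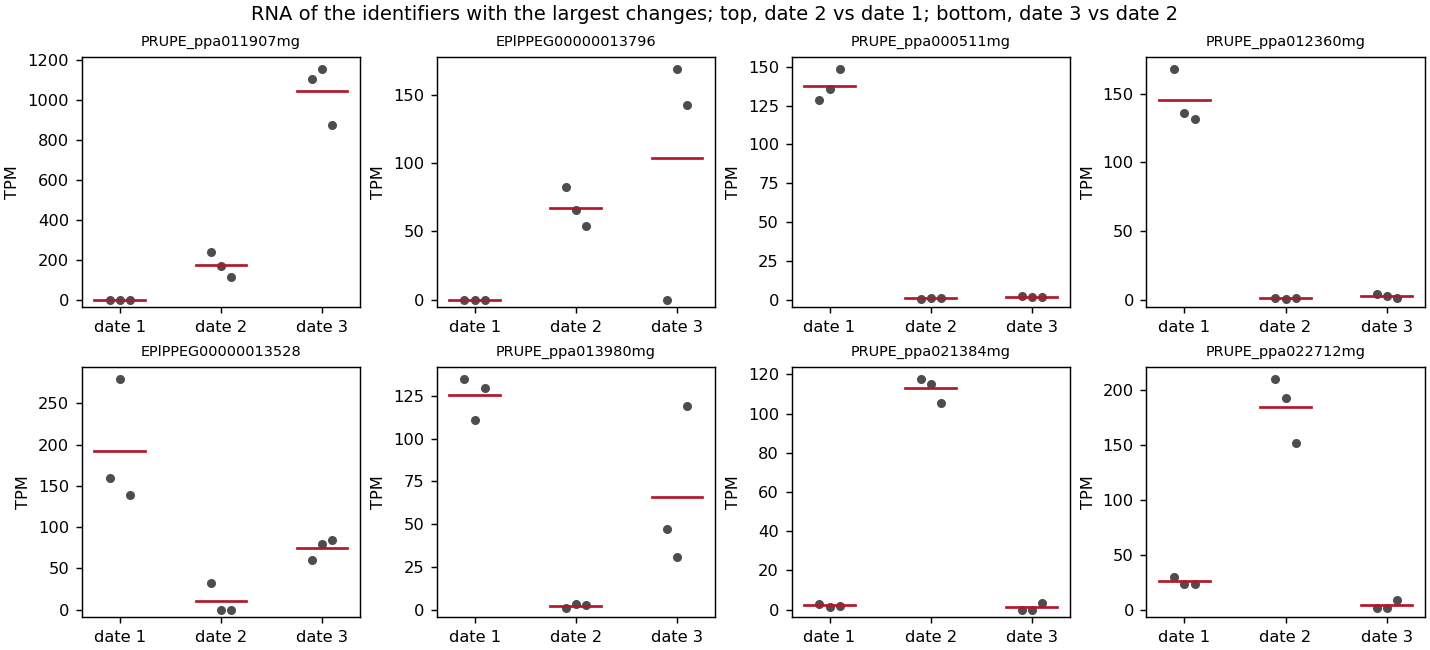
TPM of each of the 9 RNA libraries (points, with the mean of each date as a line) for the identifiers with the largest rises and falls; the top panels are for date 2 against date 1 and the bottom panels for date 3 against date 2. PRUPE_ppa011907mg climbs from at most 0.326 TPM at date 1 to at least 873 TPM at date 3, and PRUPE_ppa021384mg and PRUPE_ppa022712mg are highest at date 2.

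Set against the mean of both dormant dates, date 3 buds had 4692 genes higher and 4069 lower, 8761 in all. At 2-fold or more, 490 genes were higher and 1198 lower. The dormant mean includes October, so changes made before December enter this comparison. From date 2 to date 3 alone, 480 genes rose and 541 fell at 2-fold or more. Over the 3 dates 13206 genes changed in the limma F test, and 5660 of these (42.9%) had their highest level in October, 3352 in December and 4194 in January. Genes that moved in both intervals more often turned back than went on: 1610 fell and then rose and 1249 rose and then fell, whereas 715 rose and 736 fell in both. Independent lists of the same sizes would give 1073, 768, 981 and 840 genes in that order. A simulation without any change, keeping the shared date 2 libraries, gave 0.05 genes or fewer of each kind. It left 18383.85 of 18384 genes uncalled in both intervals on average, so its counts do not bear on the balance of turns. The covariance of the log2 fold changes of the 2 intervals was -0.0717, against -0.0243 in that simulation. With separate date 2 libraries for the intervals, 1 for one and 2 for the other, the covariance was -0.0357 to -0.0518 over the 6 ways to divide them. It stayed negative without shared libraries and was smaller in size. The counts were not computed with separate libraries, so part of the excess of turns may come from the shared ones. With library medians aligned, 4414 genes were higher and 4528 lower at date 3 than in the dormant dates, and 451 and 1266 at 2-fold or more.

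Fewer H3K4me3 changes than RNA changes were called, with 2 libraries per date against 3. Between October and December 1076 of 15360 tested regions changed in the same direction both with the deposited values and with library medians aligned. Of these, 684 had more and 392 less signal at date 2. They are nearly all of the 1083 regions called as deposited, so their balance is that of the deposited scaling. At 2-fold or more the losses were more numerous, 156 against 110 gains as deposited and 305 against 85 with library medians aligned. Among regions with at least the median signal (177.55) at the higher date, the largest gains lay on scaffold 1 at 46286378 to 46288378, with a signal of 34.05 and 60.4 in the date 1 libraries and 196 and 181 at date 2, and on scaffold 3 at 19306991 to 19308991, with 35.9 and 60.9 at date 1 and 182 and 181 at date 2. The largest losses lay on scaffold 5 at 864476 to 866476, from 179 and 179 to 51.5 and 67.4, and on scaffold 6 at 22194226 to 22196226, from 244 and 249 to 95.5 and 83.4. The median change over all regions was 0.15 on the log2(signal + 1) scale, and relative to it these regions changed by 1.88, 1.78, -1.74 and -1.60 (SE 0.22, 0.21, 0.26 and 0.16). Their adjusted p in limma (Benjamini-Hochberg) was 6.33e-05, 6.33e-05, 0.00264 and 7.35e-05, and the RNA of the gene at each changed in the same direction, by 1.90, 1.99, -3.05 and -4.52 on the log2 scale (adjusted p 4.05e-07, 3.98e-06, 8.52e-08 and 3.9e-09). The H3K4me3 call on scaffold 5 at 864476 was lost without a filter on low signal (adjusted p 0.0771). With the deposited values alone 1083 regions changed, 691 up (63.8%) and 392 down, and with library medians aligned 3523, 1811 up (51.4%) and 1712 down. The count as deposited was 228 (114 up, 114 down) without date 1 replicate 2, 474 without date 2 replicate 2, 518 (186 up, 332 down) without date 2 replicate 3, 5558 without date 3 replicate 2 and 5417 without date 3 replicate 3, and ran from 154 without a filter on low signal to 5411 with the libraries of these dates alone.

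Between December and January 261 regions changed in the same direction under both scalings, 67 up and 194 down. They are nearly all of the 266 regions called as deposited, so their balance is that of the deposited scaling. The 4 regions named next are the largest changes among those with at least the median signal at the higher date, and weaker regions with larger losses are given below with their RNA. The region on scaffold 3 at 2788510 to 2790510 went from 0.151 and 8.16 at date 2 to 198 and 181 at date 3, and the RNA of its gene rose from 13.2 ± 1.21 to 127 ± 19.6 TPM (mean ± SD, n = 3). On scaffold 1 at 13798428 to 13800428 the signal went from 106 and 44.4 to 169 and 218. The gene there spans 13799706 to 13799928, so most of the region lies outside it and the signal may not be its own. Its RNA was too low to test, at 3.47, 0 and 0 TPM at date 2 and 0 in all 3 date 3 libraries. Among the regions of that signal, losses were largest on scaffold 3 at 2762953 to 2764953, from 163 and 194 to 104 and 71.3, where the RNA log2 change was 0.07 (SE 0.10), and on scaffold 1 at 11565915 to 11567915, from 197 and 205 to 102 and 109.8, where it was -1.76 (SE 0.85). The median over all regions moved by -0.11, and relative to it these 4 regions changed by 5.99 (SE 0.96), 1.58 (SE 0.33), -0.92 (SE 0.18) and -0.81 (SE 0.16), with an adjusted p in limma (Benjamini-Hochberg) of 0.00537, 0.0313, 0.0072 and 0.00768. In the RNA, limma with Benjamini-Hochberg adjustment gave 1.05e-06 at the first, no test at the second, and 0.62 and 0.14 at the others. As deposited 266 regions changed, 67 up (25.2%) and 199 down, with medians aligned 901, 450 up (49.9%) and 451 down, and without a filter on low signal limma called 0, with 1891 at an unadjusted p under 0.05, against 171 by edgeR and 2094 by DESeq2 on the filtered regions. The deposited count was 548 without date 1 replicate 2, 540 without date 1 replicate 3, 407 without date 2 replicate 2, 165 without date 2 replicate 3, 3897 without date 3 replicate 2 and 110 (54 up, 56 down) without date 3 replicate 3. The call on scaffold 1 at 13798428 was lost in the count-based tests, with an adjusted p (Benjamini-Hochberg) of 0.0564 in limma on log2 CPM, 0.0817 in edgeR with TMM, 0.122 in edgeR with the deposited scaling and 0.122 in DESeq2. It was also lost with a pseudocount of 0.1 (0.0620) and without either replicate 3 of dates 2 and 3 (0.156 and 0.323). Its log2 change, 1.47 before the median is subtracted, was 0.84 without date 2 replicate 3 and 2.09 without date 2 replicate 2. That on scaffold 3 at 2788510, 5.88 before the median is subtracted, was 7.37 without date 2 replicate 3 and 4.38 without date 2 replicate 2. The call on scaffold 3 at 2788510 was lost with a pseudocount of 0.1 (0.0625), that on scaffold 3 at 2762953 without date 3 replicate 3 (0.0530), and all 4 without a filter on low signal (0.106 to 0.346).

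Against the mean of the dormant dates, January buds had less H3K4me3 at 1038 regions and more at 333 under both scalings. These are nearly all of the 1381 regions called as deposited, so their balance is that of the deposited scaling. The dormant mean includes October, so changes made before December enter this comparison. From December to January alone, 194 regions fell and 67 rose under both scalings. Over the 3 dates 2183 regions changed in the limma F test, and 1169 of these (53.6%) had their highest signal in October, 527 in December and 487 in January. This division is as deposited and was not computed with library medians aligned, where the F test called 5320 regions. Some regions went from the lowest value in the tables in both libraries of a date to a signal of at least 20 in both of another, or the reverse. Between October and January 54 regions lost the mark in this sense and 10 gained it. The limit of 20 was set after the data were seen, and these counts follow it. At a signal of 10 there were 104 lost and 16 gained, and at 50 there were 11 lost and 7 gained. The number of recovered reads, which covers the listed regions only, also differed between libraries, with the fewest in date 3 replicate 3 (14216613). Its effect on these counts was not tested. The RNA was lower in January for 37 of the 39 tested genes at lost regions, with a median log2 change of -1.85, and higher for 8 of the 9 at gained regions, with a median of 1.57. Between October and December 8 regions lost the mark and 5 gained it; the gains, listed after their values were seen, were on scaffold 2 at 16989531, scaffold 4 at 9600270, scaffold 5 at 5033845 and 10678180, and scaffold 8 at 16181627. Between December and January 3 regions lost it (scaffold 2 at 25743073, scaffold 3 at 8578359 and 14579554) and 0 gained it, counts that were not tested. Among tested genes at lost regions, RNA was lower for 6 of 6 from October to December and for 1 of 2 from December to January. At the regions gained from October to December it was higher for 3 of 4. A region at the lowest value in one library and at 20 or more in the other library of its date occurred 144 times at date 1, 48 at date 2 and 26 at date 3, so single-library switches are not read here. As deposited 1381 regions changed against the dormant mean, 333 up (24.1%) and 1048 down, with medians aligned 3476, 1670 up (48.0%) and 1806 down. The deposited count ran from 553 without a filter on low signal to 4540 by DESeq2, and was 2841 without date 3 replicate 2 and 2116 without date 3 replicate 3, where the majority turned (1459 up, 657 down), and the F test over dates called 1378 without date 1 replicate 2, 7290 without date 3 replicate 2 and 5917 without date 3 replicate 3.

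Genes with more H3K4me3 also had more RNA at every date. Over 12773 genes tested in both assays, the Spearman correlation of signal and TPM was 0.455 at date 1, 0.529 at date 2 and 0.547 at date 3, across genes; genes are not independent replicates. Of genes with a region of their own and a signal of at least 50, 97.7%, 97.5% and 97.8% reached 1 TPM at dates 1, 2 and 3, with medians of 31.3, 32.9 and 35.2 TPM. Of genes whose region was at the lowest value in both libraries, 30.8%, 26.4% and 27.3% did. Genes at this lowest value numbered 5831 at date 1, 6054 at date 2 and 6932 at date 3. Per library, regions at the lowest value numbered 8398, 8095 and 8392 at dates 1, 2 and 3 in replicate 2. In replicate 3 they numbered 6632, 7071 and 8334, and date 3 replicate 3 had the fewest recovered reads (14216613). The rise thus came with replicate 3, and the part of depth in it was not tested. The Spearman correlation was 0.710, 0.738 and 0.738 over all 23464 genes with a region of their own, and 0.255, 0.329 and 0.348 over genes with a mean of at least 10 TPM.

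H3K4me3 and RNA mostly moved in the same direction. From October to December 821 genes changed in both assays, and 795 of them (96.8%) did so in the same direction, 492 up and 303 down. From December to January 133 of 139 genes (95.7%) did, 46 up and 87 down, and for January against the dormant mean 806 of 841 (95.8%), 232 up and 574 down. Independent calls would put 615, 81.8 and 576 genes in both assays, and the counts of each direction would leave 432, 75.5 and 490.0 of the genes called in both with the same sign. Genes whose H3K4me3 fell from October to December had a median RNA log2 change of -1.44, those whose H3K4me3 rose 0.73, and the rest -0.02. The medians from December to January were -0.60, 0.90 and 0.03. The Spearman correlation between the log2 fold changes was 0.583 for date 2 against date 1, 0.357 for date 3 against date 2 and 0.538 for date 3 against the dormant mean, across genes, which are not independent replicates. The odds ratio of being called in both was 3.30, 2.86 and 2.94, with p = 9.55e-51, 7.97e-15 and 9.45e-62 in Fisher's exact test (two-sided), which treats genes as independent. With library medians aligned 2400, 464 and 2002 genes changed in both assays, 94.6%, 90.7% and 93.7% of them in the same direction. Without 1 H3K4me3 library at a time the share in the same direction was 86.2% to 97.5%, 74.3% to 95.6% and 90.2% to 97.2%, in each case lowest without date 3 replicate 2, while the count in both assays for date 2 against date 1 was 189 and 507 without date 1 replicates 2 and 3, 345 and 403 without those of date 2, and 3465 and 3386 without those of date 3, for date 3 against date 2 it was 223 and 220 without date 1 replicates 2 and 3, 90 without date 2 replicate 3, and 1250 and 64 without date 3 replicates 2 and 3, and against the dormant mean 1425 and 1280 without those of date 3.

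**Figure D3:**
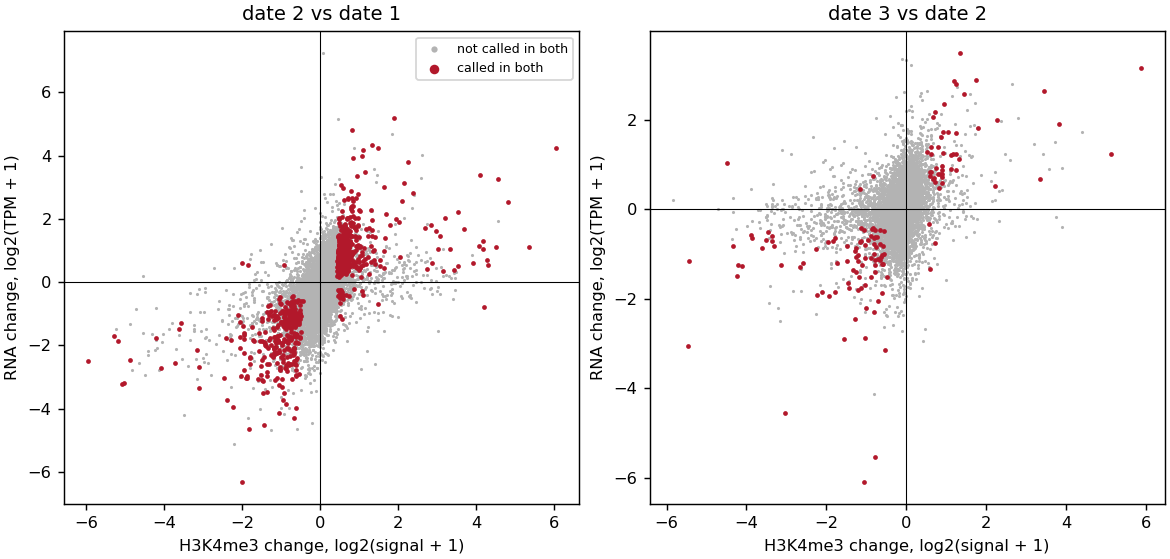
Log2 change of RNA, log2(TPM + 1), against log2 change of H3K4me3, log2(signal + 1), for each of 12773 genes tested in both assays, with genes called in both in red; left, date 2 against date 1, and right, date 3 against date 2. Most red points lie in the lower left and upper right, 795 of 821 and 133 of 139.

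Many large RNA changes came without a called H3K4me3 change. Of 87 genes whose RNA rose at least 4-fold from October to December, 49 (56.3%) also gained H3K4me3, and of 295 whose RNA fell as much, 108 (36.6%) lost it. From December to January the counts were 10 of 37 (27.0%) and 11 of 38 (28.9%). As groups these genes moved in H3K4me3 with their RNA, called or not: relative to all genes the median H3K4me3 log2 change was 0.65 for the rises and -1.02 for the falls from October to December, and 0.67 and -0.52 from December to January. With 2 libraries per date, a missing call does not show a lack of change. PRUPE_ppa011907mg had an H3K4me3 signal of 6.77 and 14.2 at date 1 and 8.16 and 13.4 at date 2, while its RNA reached 173 ± 61.3 TPM (mean ± SD, n = 3). At date 3 its signal was 123 and 124 and its RNA 1044 ± 151 TPM. At PRUPE_ppa000511mg the signal fell with the RNA, from 165 and 186 to 40.2 and 46.1. The H3K4me3 change of PRUPE_ppa000511mg from date 1 to date 2 was -2.15 relative to the median (SE 0.22), with an adjusted p of 6.66e-05 (limma, Benjamini-Hochberg). The 49 rises with a gain were 30 without date 1 replicate 2 of H3K4me3, and the 108 falls with a loss were 45 without it, 65 without date 1 replicate 3 and 57 without date 2 replicate 2, but 159 of 294 (54.1%) without date 3 replicate 2 and 156 of 294 (53.1%) without date 3 replicate 3, a majority. In the later interval the 10 rises were 16 without date 1 replicate 2 and 6 without date 3 replicate 3, and the 11 falls were 6 without date 2 replicate 2, 5 without date 2 replicate 3, 19 without date 3 replicate 2 and 6 without date 3 replicate 3.

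The largest joint changes lay at the following loci. The region on scaffold 4 at 9600270 to 9602270 was at the lowest value in both date 1 libraries, then at 70.4 and 81.2, and the RNA of its gene rose from 2.20 ± 0.225 to 60.1 ± 7.40 TPM (mean ± SD, n = 3). On scaffold 4 at 7012836 to 7014836 the signal went from 0.183 and 12.3 to 88.7 and 97.5 and the RNA from 2.16 ± 0.584 to 29.2 ± 4.59 TPM. On scaffold 3 at 18157035 to 18159035 the signal fell from 93.5 and 89.9 to 0.151 and 5.44 and the RNA from 20.4 ± 1.55 to 1.29 ± 0.258 TPM. On scaffold 1 at 7495141 to 7497141 it fell from 52.2 and 49.2 to 0.151 and 1.13, and the RNA from 65.1 ± 4.37 to 6.23 ± 1.14 TPM. From date 2 to date 3, besides the rises on scaffold 3 at 2788510 and scaffold 1 at 1499480 described above, signal and RNA fell on scaffold 4 at 6476560 to 6478560, from 77.3 and 78.0 to 1.72 and 0.185 and from 9.78 ± 2.42 to 0.273 ± 0.0706 TPM. They also fell on scaffold 1 at 11693184 to 11695184, from 135 and 117 to 16.4 and 12.6 and from 47.5 ± 6.71 to 1.16 ± 0.814 TPM. For the 4 loci of dates 1 and 2 the adjusted p of H3K4me3 was 5.63e-06, 0.000965, 0.0115 and 0.00633 and that of RNA 3.93e-07, 1.63e-07, 5.49e-07 and 5.22e-08 (limma, Benjamini-Hochberg). For the falls from date 2 to date 3 it was 4.33e-06 at both for H3K4me3 and 2.64e-06 and 1.25e-06 for RNA (limma, Benjamini-Hochberg).

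**Figure D4:**
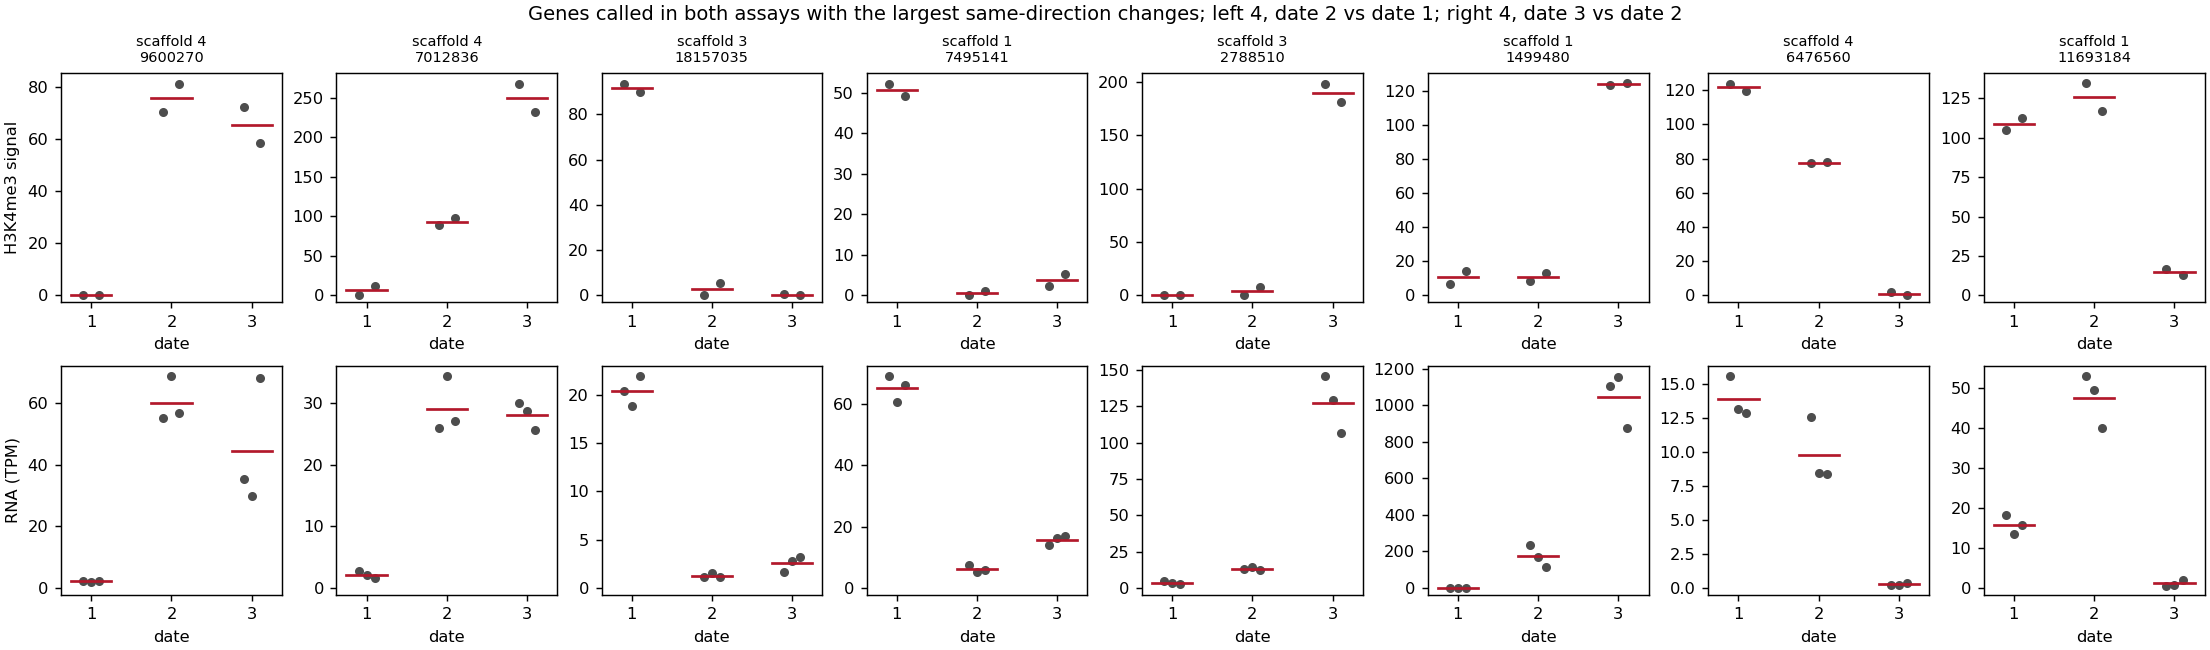
H3K4me3 signal of each of 6 libraries (top) and TPM of each of 9 RNA libraries (bottom) by date, with date means as lines, at 8 loci named by scaffold and start of the region; the left 4 changed most from date 1 to date 2 and the right 4 from date 2 to date 3. On scaffold 1 at 1499480 the RNA rises at date 2 and the H3K4me3 signal, 123 and 124, only at date 3.

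A set of 671 regions carries a gene identifier in the H3K4me3 tables and is listed before the others. Of these, 488 had their highest mean signal in October, 111 in December and 72 in January, and their median signal was 16.7, 10.6 and 1.59 at dates 1, 2 and 3. Against the dormant mean, 49 rose and 208 fell in H3K4me3 at date 3 (51 and 217 with medians aligned). In the RNA, 85 rose and 262 fell from October to December (89 and 263 with medians aligned), among 461 tested. Over the dates 280 of 509 tested regions changed (55.0%), against 1903 of 14851 others (12.8%). Why these regions carry identifiers is not given in the sources used here. If the study chose them on these libraries, neither this larger share nor their direction is independent evidence.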

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

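Alternatives chosen only after the data were seen were, for H3K4me3, recomputed TMM, median alignment, both edgeR fits, the filters at a signal of 50 and above the lowest value, and both pseudocounts, and, for correlations and levels, the edgeR values, all genes with a region and the left-out libraries. RNA counts stayed within 1.5 times under every alternative but the 2-fold threshold, which by construction left 3410, 1021, 1688 and 4874 genes (date 2 against date 1, date 3 against date 2, date 3 against the dormant mean, any date; this order holds throughout). Leaving out 1 library gave 9750 to 11381, 4852 to 5852, 7136 to 8559 and 11921 to 13214 genes.

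H3K4me3 counts moved with scaling, and the cause was not tested directly. They were 3440, 885, 3299 and 5091 with total reads, 3280, 859, 3314 and 5018 with DESeq2 size factors, 3360, 867, 3376 and 5147 with recomputed TMM, and 3523, 901, 3476 and 5320 with medians aligned. The share of rises, 63.8%, 25.2% and 24.1% as deposited, was 48.7%, 46.9% and 42.0% with total reads, 47.5%, 49.9% and 45.4% with size factors, 1714 of 3360, 435 of 867 and 1611 of 3376 with TMM, and 51.4%, 49.9% and 48.0% with medians aligned. By other tests they were 3320, 845, 3249 and 4979 with limma on log2 CPM, 3034, 758, 3030 and 4602 with edgeR and TMM, and 4546, 2094, 4540 and 6677 with DESeq2. edgeR with the deposited scaling gave 561, 171 and, for any date, 1440. Without a filter limma gave 154, 0 (1891 at an unadjusted p under 0.05), 553 and 610. A signal of at least 50 gave 2199 and 590 for adjacent dates, regions above the lowest value 1785 and 460, and the compared dates alone 5411 and 515. For date 2 against date 1 the full fit called 1083, so including the date 3 libraries, which share the spread, lowered that count. As deposited, the 2 date 3 libraries differed by a median of 0.26 log2 units. A pseudocount of 0.1 gave 166 for date 3 against date 2. Leaving out 1 library gave 228 to 5558, 110 to 3897, 1119 to 2841 and 1378 to 7290. The lone library of a date was then assumed to vary like the others. The lowest were without date 1 replicate 2, date 3 replicate 3, date 2 replicate 3 and date 1 replicate 2, and each highest was without date 3 replicate 2.

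The replicate block gave 10803, 5459, 8229 and 12803 RNA genes and 1159, 542, 1512 and 2430 H3K4me3 regions. The labels pair no libraries, and numbers were not taken as pairs because not every pair of dates correlated: same-numbered RNA libraries deviated from their date means with r of -0.0857 to 0.105, and H3K4me3 libraries with 0.529 (dates 1 and 2), -0.0683 (dates 1 and 3) and -0.102 (dates 2 and 3). So H3K4me3 replicates 2 and 3 differed alike at dates 1 and 2. There replicate 2 was the lower library in all 144 and all 48 regions with 1 library at the lowest value and the other at 20 or more, against 7 of 26 at date 3. Replicate 2 also had fewer recovered reads at dates 1 and 2 (14898960 against 18279008, and 19724516 against 28126160). At date 3 it had more (23871977 against 14216613). The number of recovered reads and the replicate number were not told apart here.

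The Spearman correlation between changes was 0.645 (date 2 against date 1) and 0.606 (date 3 against the dormant mean) over RNA-called genes, 0.556 and 0.519 over genes of at least 10 TPM, and for the dormant mean 0.517 with replicates 2 and 3 alone and 0.541 with edgeR. Without 1 library it was 0.537 to 0.584, 0.316 to 0.378 and 0.495 to 0.544. The correlation between levels at dates 1, 2 and 3 was 0.710, 0.738 and 0.738 over all genes with a region, 0.431, 0.518 and 0.536 over RNA-called genes, and 0.255, 0.329 and 0.348 at 10 TPM or more; without 1 library it was 0.451 to 0.456, 0.521 to 0.533 and 0.541 to 0.550. The cause was not tested. Of 309 alternative values for the 16 named items of single assays, 294 kept their direction and call, 15 lost the call, 14 of them in H3K4me3, and 0 reversed. Gained and lost regions numbered 9 and 22, 4 and 19, and 16 and 104 (dates 1 to 2, 2 to 3, 1 to 3) at a signal of 10, and 1 and 1, 0 and 1, and 7 and 11 at 50.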

Other observations

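The observations in this part were chosen after the data were seen, and the tests after their own results were seen, except the test with separate date 2 RNA libraries and the test within 4 ranges of signal. Some genes were expressed while their start stood at the lowest H3K4me3 value; whether a control had been subtracted there is not given in the sources used here. Of 23464 genes with a region of their own, 5015 were at the lowest H3K4me3 value in all 6 libraries, and 702 of these had a mean of at least 10 TPM (52 of them at least 100 TPM). They made up 6.34% of the 11075 genes at that level. Their median was 28.0 TPM, against 39.8 TPM for the other genes of that level, and their median locus 2510 bp against 3007 bp. RNA changed over the dates in 67.9% of these and 78.8% of the other genes, a difference that was not tested. A range of at least 4-fold between date means was reached by 5.27% and 5.09%. Identifiers beginning with EPlPPEG covered short loci, with a median of 99 bp against 2055 bp for those beginning with PRUPE. Of 130 tested, 22 rose and 19 fell from October to December, and 4 rose and 24 fell from December to January (4 and 25 with library medians aligned). Their libraries of one date differed more, with a median within-date SD of 1.27 log2 units against 0.16 for PRUPE identifiers. They took 1.11% to 1.83% of the TPM of a library.

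Some neighbouring genes changed together in the RNA. Neighbours are taken in the order of the deposited coordinates, which need not be their order in the sweet cherry genome. The Spearman correlation of neighbours' changes was 0.120 from October to December and 0.096 from December to January. From October to December 35 runs of at least 4 consecutive tested genes changed 2-fold or more in the same direction, 34 of them falling. They held 167 of the 3386 genes among these 18254 that changed as much. The longest falling runs held 8 genes each, on scaffold 1 at 38497391 to 38654036 (mean 72.5, 6.40 and 16.2 TPM over the dates) and on scaffold 8 at 12279537 to 12370361 (862, 285 and 84.5 TPM). The rising run lay on scaffold 1 at 1492602 to 1508860 and held PRUPE_ppa011907mg (4 genes, mean 20.2, 160.0 and 558 TPM). From December to January there were 3 runs, with 13 of the 998 genes among the 18254 that changed 2-fold or more. They lay on scaffold 6 at 18614876 to 18635828 (falling) and, rising, on scaffold 1 at 38155413 to 38195504 and scaffold 3 at 17411816 to 17437449.

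The tables argue against chance order as the source of these runs: the 35 runs compare with a mean of 4.52 and a highest of 12 in 1000 shuffles of gene order (one-sided permutation p = 0.001, the smallest these shuffles can give). Transcription running on into the next gene is argued against for neighbours on the same strand over 10 kb apart, where the Spearman correlation of their changes from October to December was 0.2321 (0.190 to 0.276 in a bootstrap that treats pairs as independent), above that of same-strand pairs under 2 kb apart, 0.0973 (0.0572 to 0.140). From December to January the values were 0.1558 and 0.112, and the bootstrap range of their difference (-0.108 to 0.0139, under minus over) includes 0. For these later changes, and for pairs under 2 kb apart, running on cannot be told apart from separate transcription, because positions of reads were not used here. Reads shared between tandem copies on one strand by definition leave out neighbours on opposite strands. Convergent pairs had a correlation of 0.0547 (0.0187 to 0.0914 in a bootstrap that treats pairs as independent), which such copies leave unexplained. This value does not test such copies for pairs on the same strand, and copies on opposite strands were not tested. For neighbours on the same strand, with a correlation of 0.1714, tandem copies cannot be told apart from separate genes that change together, because no gene sequences were used here. Shared regulation of neighbouring genes is a candidate explanation that was not tested.

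The 2 H3K4me3 libraries of date 3 differed across all regions, by a median of 0.26 log2 units (replicate 2 minus replicate 3), against -0.05 at date 1 and -0.10 at date 2. A difference confined to weakly marked regions is argued against by the most strongly marked of 4 equal groups of regions, where it was 0.2579. A single factor on every region of a library as the only difference is argued against by the group with the least signal, where the difference was 0.1276 (0.109 to 0.148 in a bootstrap that treats regions as independent). In that group replicates also differed at dates 1 and 2, by -0.369 and -0.332, so a factor on every region together with a separate difference in weakly marked regions is not excluded. For the other 3 groups a single factor is consistent with the values, since the difference varied by 0.0184 over them. Such a factor may account for the larger H3K4me3 counts under other scalings, such as 3440 against 1083 regions for date 2 against date 1. At each date the library with fewer recovered reads had the lower signal by this median difference. Replicates 2 and 3 held 14898960 and 18279008 reads at date 1, 19724516 and 28126160 at date 2, and 23871977 and 14216613 at date 3. Scaled by the total of these reads, the date 3 difference was -0.0038. Such scaling removes a factor common to a library's regions whatever its source. The source of the factor, a different share of reads outside the regions, the deposited scaling or the buds, stays open and was not tested.

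H3K4me3 change from December to January was weakly correlated with RNA change from October to December. The Spearman correlation was 0.112 with all libraries, 0.115 and 0.052 with replicates 2 and 3 alone, and 0.033 to 0.124 within 4 equal groups by signal. The partial Spearman correlation given the RNA change from December to January was 0.2056 across 12773 genes, which are not independent replicates, and 0.202 and 0.170 with replicates 2 and 3 alone. Chance values of the date 2 RNA libraries, shared by both RNA changes, are argued against by the fits with separate date 2 libraries, whose lowest value was 0.1529, and a trend with signal by the 4 groups of regions, whose lowest was 0.1592. H3K4me3 that follows RNA with a delay is consistent with this: for genes whose RNA fell at least 2-fold and then stayed within 0.25 log2 units, the median later H3K4me3 change differed from that of all genes by -0.11 to -0.16 log2 units, and for those whose RNA rose as much and then stayed, by 0.037 to 0.081. It remains a hypothesis found and tested on the same libraries, and the correlation in the other order, earlier H3K4me3 with later RNA, given earlier RNA, was 0.108 (0.150 and 0.052 with replicates 2 and 3 alone), and the difference between the orders was not tested. The partial correlation did not hold the earlier H3K4me3 change fixed, which itself went with the earlier RNA change (Spearman correlation 0.583). In both intervals 27 called regions fell and 11 rose, against 5.08 and 3.01 for independent lists. Another 1 rose and then fell and 11 fell and then rose, against 8.95 and 1.71. A delay was therefore not told apart from H3K4me3 changes that continue in one direction.

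Other splits of the RNA libraries gave fewer called genes, with 1 exception. For date 2 against date 1, 1 of the 10 splits, the real one, called as many genes (11117, highest of the others 1), and for date 3 against date 2 also 1 of 10 (6056, highest of the others 4), where 10 splits are too few for a share under 0.05. For any date 1 of 100 splits, the real one, called as many (13206, highest of the others 741), a share under 0.05. For date 3 against the dormant mean 2 of 100 splits did (8761, highest of the others 9722), also a share under 0.05. Such shares show that the counts are rare among these splits. The splits treat libraries as exchangeable, and whether replicates came from separate trees is not given. The split with 9722 genes set the 3 date 1 libraries apart, a structure of the samples by date, and the next highest called 13.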
